A study of Drosophila melanogaster with 9 samples.

How the data were processed

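Gene expression was measured by RNA sequencing in Malpighian (renal) tubules of Drosophila melanogaster. Per the labels, virgin progeny were kept at 18 °C for 6 to 8 days and then at 29 °C for 8 days, which induces the transgenes. RNA came from 80 tubules per genotype, was enriched for poly-A transcripts and was made into Illumina TruSeq libraries. The 3 groups hold 3 libraries each. Control flies carried esg-Gal4, tub-Gal80ts and UAS-GFP. The yki3SA flies also carried UAS-Yki-3SA, an activated form of the growth regulator Yorkie, and the yki3SA+ITP-i flies (called ITP-i from here on) also carried an RNAi transgene against the hormone gene ITP. The labels do not say whether libraries of a group came from separate fly cultures or dissections. The sample titles mark the control and yki3SA libraries as re-analysed and the ITP-i libraries not, so a batch may coincide with the ITP-i genotype. No group carries a neutral RNAi transgene, so the number of UAS transgenes differs between the groups as well.

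The deposited table holds raw counts per gene, 1 column per library, with no normalization by the authors. It was checked that the values are whole numbers with a different total in each column. The submitters' processing notes name TopHat, Cufflinks, HTSeq and DESeq, and give no version, role or order for them. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. The table lists 17611 genes, of which 17552 FlyBase identifiers were matched to a symbol and 59 were not. A pathway column of the same table was used to form 264 pathways with at least 10 tested genes, a choice made after the data were seen. The Ensembl reference annotation (a copy whose build may differ from the authors') served only to find which genes are neighbours among the genes tested.

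Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries were scaled with TMM factors, and the 9 libraries were fitted together with a term for group, which leaves 6 residual degrees of freedom. The quasi-likelihood F-test (robust = FALSE) was run for each pair of groups. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over the 10253 genes tested. Expression levels of single genes are CPM scaled with the TMM factors, as mean ± SD of 3 libraries, and log2 fold changes come from the edgeR fit with a prior count of 0.125. Sums over gene lists are CPM of total counts over every member in the table. Where a group had no count in any library, the fold is a lower bound against 3 counts in the smallest library, 0.0866 CPM. Such floors cover counting error only. A gene "moved back" when it was called in yki3SA against control and called in the opposite direction in ITP-i against yki3SA, and it "moved further" when both calls went the same way.

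Gene lists for renal transport, immunity, metabolism, growth and cell types were written before the data were examined. They are 31 lists with 1079 names, of which 1069 genes were found, and 30 lists had at least 5 tested members. Lists were compared with all other tested genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 30 lists. An estimated correlation and fry were run as alternatives. For each list the members called are counted over all genes tested and adjusted over the list alone. The named genes follow a rule also written before the data were examined. It takes yki and ITP. For yki3SA against control and for ITP-i against yki3SA, it takes the 8 largest rises and 8 largest falls and the next 4 in each direction with a named symbol, among called genes with at least 10 CPM in the higher group and no overlap between the libraries of the groups. It takes 4 rises and 4 falls in the same way for ITP-i against control, up to 4 members per list (2 rises and 2 falls with the smallest p), and the 8 genes that moved back with the smallest p. Chance alone separates the libraries of 10% of genes with 3 libraries against 3.

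Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile and total-count scaling, no filter, at least 5 CPM in 3 libraries, robust = TRUE, fits with only 2 groups, a fold of at least 2, a block for the replicate number, and fits without each library in turn. Chosen after the data were seen were fits with the fat body or gut marker level as a covariate, without the marker genes of other tissues, and without both tumour libraries numbered 3. For counts of genes and lists, other splits of the libraries were refitted (10 for each pair of groups, and 100 drawn of the 840 splits of the 9 libraries for genes that moved back). Counts were also simulated 25 times with the fitted means and dispersions, to see what shared libraries alone give. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

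The count test was tested on simulated data with the real library sizes, in which 9776 of the 10031 genes tested were unchanged. Against control, edgeR recovered 7.7% of genes with a 1.5-fold change, 51.6% with a 2-fold change and 74.6% with a 4-fold change, and 4.4% of its calls were on unchanged genes. DESeq2 recovered 26.2%, 67.2% and 85.7%, with 15.3% of its calls on unchanged genes, and limma-voom recovered 6.2%, 50.0% and 71.4%, with 5.7%. The camera test recovered the 1 list that had been shifted and called 0 of the other lists. The simulated genes were independent of each other, so this does not test how camera behaves on lists of correlated genes. Total counts per library were 34640437 to 49338340, so that 3 counts correspond to 0.0608 to 0.0866 CPM. No sample was left out. The labels' mention of meta-sequencing concerns data not used here.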

Results

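Polyadenylated RNA of Malpighian tubules, the renal organ of the fly, was sequenced in 9 libraries, 3 each from control flies, from flies with a yki3SA tumour and from flies with a yki3SA tumour and ITP knockdown (ITP-i). The driver gene esg is expressed in progenitor cells of the gut and also in stem cells of the tubules. Total counts were 45728599, 39213686 and 36088638 in control, 34640437, 40867555 and 49338340 in yki3SA and 41978250, 40962290 and 41123890 in ITP-i. The 10 most abundant genes took 16% to 17% of the counts in control, 12% to 13% in yki3SA and 15% to 16% in ITP-i. TMM factors were 0.88 to 0.95 in control, 1.06 to 1.21 in yki3SA and 0.94 to 1.03 in ITP-i.

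ITP (FBgn0035023), which encodes the antidiuretic ion transport peptide and is the target of the knockdown, was measured at 37.0 ± 6.70 CPM in control tubules, 68.4 ± 10.4 CPM in yki3SA and 58.6 ± 6.21 CPM in ITP-i. Per library it was 32.7, 33.5 and 44.7 CPM in control, 56.8, 77.0 and 71.2 CPM in yki3SA and 51.7, 63.7 and 60.4 CPM in ITP-i. It rose in yki3SA against control (log2 fold change 0.89, SE 0.16, adjusted p = 0.003), a call that ended with the fat body (log2 1.18, adjusted p = 0.11) or gut marker level (log2 0.83, adjusted p = 0.16) as a covariate. The difference of ITP-i from yki3SA did not pass the test (log2 -0.22, SE 0.16, adjusted p = 0.35), so no lower ITP transcript level was detected in tubules of knockdown flies. Against control, ITP was higher in ITP-i (log2 0.67, adjusted p = 0.027), a call that ended without control library 1 or 2 or ITP-i library 2 or 3 (log2 0.57, 0.59, 0.59 and 0.65). It also ended with the fat body (adjusted p = 0.053) or gut marker level (adjusted p = 0.21) as a covariate and without both tumour libraries numbered 3 (adjusted p = 0.073). The RNAi transgene is driven in esg-positive cells, and a knockdown there was not measured in these libraries. yki (FBgn0034970) was at 73.3 ± 8.96, 83.0 ± 7.61 and 77.9 ± 9.04 CPM in control, yki3SA and ITP-i, with no call in yki3SA against control (log2 0.18, adjusted p = 0.34). Its libraries were at 78.1, 63.0 and 78.8 CPM in control, 84.6, 89.7 and 74.7 CPM in yki3SA and 84.6, 81.4 and 67.6 CPM in ITP-i.

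**Figure D1:**
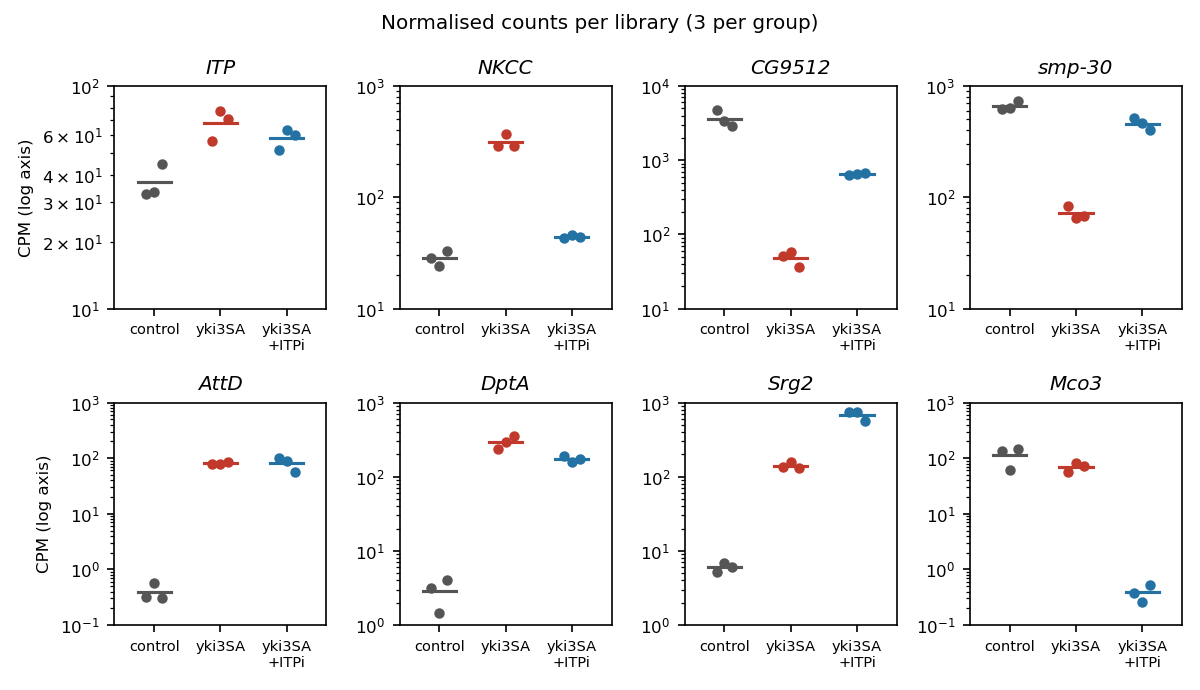
Normalised CPM of 8 genes on log axes, with 1 point per library and a bar at the mean of each group (3 libraries each). NKCC rose from 28.5 CPM in control to 315 CPM in yki3SA and was at 44.1 CPM in ITP-i, AttD was near 80 CPM in both tumour groups (80.3 and 81.5 CPM), and Mco3 was at 0.385 CPM in ITP-i against 114 CPM in control.

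The comparison of yki3SA with control asks how renal tubules differ in flies that carry the tumour. Of the genes tested, 48 of 63 for oxidative phosphorylation, 19 of 25 of the TCA cycle and 75 of 83 for cytosolic ribosomal proteins fell. Of 35 proteasome genes 30 rose, and 11 of 25 antimicrobial peptide genes rose while 2 fell. Smaller parts of the organic solute transport (13 of 35), ion and water transport (13 of 41), cytochrome P450 (22 of 68) and glutathione S-transferase and UDP-glycosyltransferase lists (21 of 58) fell, with 3, 3, 5 and 4 genes risen. Each of these list calls was lost with an estimated correlation between genes (adjusted p = 0.16 to 0.42). NKCC (FBgn0051547), a sodium-potassium-chloride cotransporter, rose from 28.5 ± 4.18 to 315 ± 48.1 CPM (log2 3.47, SE 0.15, adjusted p = 9.0e-07, higher in 3 of 3 libraries). In all, 3091 of 10253 genes were called, 1659 higher and 1432 lower, and 1293 of these differed at least 2-fold (526 higher, 767 lower). In the same libraries 9 of 16 fat body, 26 of 47 gut and 16 of 24 ovary markers fell, from organs that lie beside the tubules.

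Of 63 oxidative phosphorylation genes tested, 48 fell and 1 rose (50 and 1 adjusted over the list alone). The median log2 fold change was -0.51 (camera, adjusted p = 1.6e-11, or adjusted p = 0.41 with an estimated correlation). ATPsynC, a subunit of the ATP synthase, fell from 2402 ± 231 to 1174 ± 133 CPM. Of 25 TCA cycle genes, 19 fell and 1 rose (21 and 1 over the list alone). Their median was -0.68 (adjusted p = 2.7e-10, or adjusted p = 0.3 with an estimated correlation). The aconitase mAcon1 fell from 2118 ± 135 to 682 ± 32.3 CPM. Pepck2, which makes phosphoenolpyruvate for gluconeogenesis, was the 1 member that rose, from 3.57 ± 0.521 to 10.1 ± 3.11 CPM, a call that ended without control library 1 or 3 or yki3SA library 1, with limma-voom and with either covariate. Of 83 cytosolic ribosomal protein genes, 75 fell and 0 rose (81 and 0 over the list alone). The list median was -0.54 (adjusted p = 7.4e-15, or adjusted p = 0.42 with an estimated correlation). RpS2 fell from 1636 ± 83.6 to 915 ± 158 CPM. Of 35 proteasome genes, 30 rose and 0 fell (32 and 0 over the list alone). The members' median was 0.54 (adjusted p = 2.3e-09, or adjusted p = 0.37 with an estimated correlation). Rpt6R rose from 2.69 ± 0.583 to 16.4 ± 2.26 CPM and Prosalpha7 from 61.9 ± 4.80 to 111 ± 10.7 CPM. With total-count scaling the medians were -0.22 for oxidative phosphorylation, -0.39 for the TCA cycle, -0.26 for ribosomal proteins and 0.83 for the proteasome. In these libraries the summed level of 16 fat body markers was 317 ± 132 CPM in yki3SA against 3891 ± 1550 CPM in control.

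Of 25 antimicrobial peptide genes, 11 rose and 2 fell (11 and 4 over the list alone). The median log2 fold change was 1.84 (adjusted p = 1.2e-08, or adjusted p = 0.29 with an estimated correlation). The attacin AttD (FBgn0038530) rose from 0.396 ± 0.145 to 80.3 ± 5.24 CPM (log2 7.65, SE 0.31, adjusted p = 5.5e-07). The diptericins DptA and DptB rose from 2.88 ± 1.32 to 291 ± 59.4 CPM and from 2.79 ± 1.46 to 86.6 ± 11.4 CPM, and the drosocin gene Dro rose from 0.226 ± 0.283 to 14 ± 6.26 CPM. Of 33 components of the IMD and Toll immune pathways, 12 rose and 5 fell (13 and 5 over the list alone). Their median was 0.15 (adjusted p = 0.019, or adjusted p = 0.29 with an estimated correlation). The recognition protein gene PGRP-SD rose from 1.45 ± 0.517 to 19.7 ± 2.77 CPM and pirk, a negative regulator of the IMD pathway, from 10.4 ± 2.02 to 53.9 ± 3.81 CPM. GNBP1, which acts upstream of Toll, fell from 25.6 ± 2.84 to 7.67 ± 1.38 CPM. The median of the IMD and Toll list was 0.45 with total-count scaling, 0.10 with upper-quartile scaling and 0.09 with DESeq2 size factors. Its call ended without yki3SA library 2 (adjusted p = 0.064) and with the fat body marker level as a covariate (adjusted p = 0.05).

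Of 35 organic solute transporter genes, 13 fell and 3 rose (16 and 3 over the list alone). The list median was -0.56 (adjusted p = 3.4e-04, or adjusted p = 0.3 with an estimated correlation). The pigment precursor transporter gene st fell from 1057 ± 126 to 381 ± 34.5 CPM and the organic anion transporter gene Oatp58Da from 669 ± 96.6 to 232 ± 32.1 CPM. Of 41 ion and water transport genes, 13 fell and 3 rose (16 and 3 over the list alone). The members' median was -0.37 (adjusted p = 0.0012, or adjusted p = 0.35 with an estimated correlation). The potassium channel gene Irk3 fell from 2754 ± 165 to 986 ± 66.3 CPM and Eglp2, of the aquaporin family, from 359 ± 80.9 to 54.6 ± 13.4 CPM, while Ncc69, a second cation-chloride cotransporter gene, rose from 9.44 ± 1.60 to 20.3 ± 6.73 CPM. That call ended with the fat body (adjusted p = 0.05) or gut marker level (adjusted p = 0.074) as a covariate. Of 68 cytochrome P450 genes, 22 fell and 5 rose (25 and 8 over the list alone). The median was -0.44 (adjusted p = 6.5e-04, or adjusted p = 0.3 with an estimated correlation). Cyp6g1, known from insecticide resistance, fell from 2180 ± 729 to 71.4 ± 14.3 CPM, and Cyp6a14 rose from 44.4 ± 9.85 to 175 ± 41.5 CPM. Of 58 glutathione S-transferase and UDP-glycosyltransferase genes, 21 fell and 4 rose (21 and 4 over the list alone). Their median was -0.59 (adjusted p = 1.1e-06, or adjusted p = 0.16 with an estimated correlation). Ugt37B1 fell from 38.2 ± 11.6 to 0.915 ± 0.319 CPM. Of 13 markers of principal cells, the main transporting cell type of the tubule, 5 fell and 0 rose (5 and 0 over the list alone). The list median was -0.47 (adjusted p = 3.5e-04, or adjusted p = 0.31 with an estimated correlation), and 11 of the 13 are also members of another list. With total-count scaling the medians were -0.28 for organic solute transporters, -0.07 for ion and water transport, -0.15 for cytochrome P450s, -0.32 for the transferases and -0.20 for principal cells. The fat body and gut markers fell in these same libraries.

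The lipid metabolism list was called at adjusted p = 0.043 (or adjusted p = 0.52 with an estimated correlation), with a median of -0.30, 16 of 41 genes fallen and 4 risen (18 and 4 over the list alone). Its summed level in CPM of total counts, a scale on which the median was -0.02, was higher (6003 ± 127 CPM in control and 7589 ± 258 CPM in yki3SA). The lipocalin gene NLaz rose from 272 ± 26.5 to 902 ± 140 CPM and its relative GLaz fell from 42.3 ± 12.9 to 11.5 ± 1.30 CPM. This call ended without yki3SA library 3 (adjusted p = 0.2), without ITP-i library 3 (adjusted p = 0.051), with a block for the replicate number (adjusted p = 0.076), with total-count scaling (median -0.02, adjusted p = 0.15), with a filter of 5 CPM (adjusted p = 0.076) and with the fat body or gut marker level as a covariate (adjusted p = 0.36 and 0.076). The glycolysis list was called at adjusted p = 0.013 (or adjusted p = 0.68 with an estimated correlation), with 6 of 22 genes fallen and 0 risen (9 and 0 over the list alone) and a median of -0.26 that turned to 0.03 with total-count scaling. Its summed level was 14299 ± 1524 and 13702 ± 387 CPM. UGP, which makes UDP-glucose, fell from 1001 ± 206 to 304 ± 63.8 CPM. That call ended with total-count scaling (adjusted p = 0.11), without control library 1 (adjusted p = 0.087), without yki3SA library 3 (adjusted p = 0.065) and with the gut marker level as a covariate (adjusted p = 0.55). Of 35 cell cycle and DNA replication genes, 3 rose and 0 fell, with adjusted p = 0.48. Their summed level was 367, 359 and 1263 CPM in the yki3SA libraries, 400, 331 and 742 CPM in ITP-i and 378 ± 10.3 CPM in control. The third library was also the highest of each tumour group in ovary and early embryo markers (53, 41 and 162 CPM in yki3SA and 213, 96 and 283 CPM in ITP-i). Without yki3SA library 3 the list was called lower (adjusted p = 0.046), and without yki3SA library 1 or 2 it was called higher (adjusted p = 0.043 and 0.045).

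Of 16 fat body marker genes, 9 fell and 1 rose (11 and 1 over the list alone). The members' median was -3.14 (adjusted p = 1.4e-07, or adjusted p = 0.3 with an estimated correlation). The yolk protein gene Yp2 fell from 1305 ± 575 to 53.5 ± 17 CPM and the odorant-binding protein gene Obp99a from 26.4 ± 10.7 to 0.298 ± 0.176 CPM. Of 47 gut enterocyte markers, 26 fell and 4 rose (30 and 4 over the list alone). The median was -3.54, or -3.32 with 4 members that had no count in one of the groups set to their bound (adjusted p = 6.5e-10, or adjusted p = 0.3 with an estimated correlation). Their summed level was 950 ± 403 CPM in control and 207 ± 110 CPM in yki3SA. The lysozyme gene LysD fell from 93.4 ± 59.7 to 1.13 ± 1.23 CPM and the protease gene Bace from 147 ± 95.1 to 2.23 ± 1.83 CPM. Jon66Cii, a serine protease gene, had no count in control and was at 0.701 ± 0.209 CPM in yki3SA. Lysozyme, trypsin and Jon proteases are families of near-identical genes, whose reads are hard to assign. Of 24 ovary and early embryo markers, 16 fell and 0 rose (16 and 1 over the list alone). Their median was -4.68 (adjusted p = 3.6e-06, or adjusted p = 0.31 with an estimated correlation). The chorion genes Cp38 and Cp36 fell from 26.8 ± 18.3 to 0.307 ± 0.383 CPM and from 17.8 ± 13.3 to 0.297 ± 0.499 CPM. Of 16 hemocyte markers, 8 fell and 2 rose (8 and 2 over the list alone). The list median was -0.96 (adjusted p = 0.02, or adjusted p = 0.37 with an estimated correlation). On the scale of total counts the median was -0.67, while the summed level did not fall (301, 326 and 374 CPM in the control libraries and 316, 381 and 362 CPM in yki3SA). This call ended without control library 3 (adjusted p = 0.059), with the replicate block (adjusted p = 0.05), with a filter of 5 CPM (adjusted p = 0.16) and with the fat body or gut marker level as a covariate (adjusted p = 0.51 and 0.066).

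**Figure D2:**
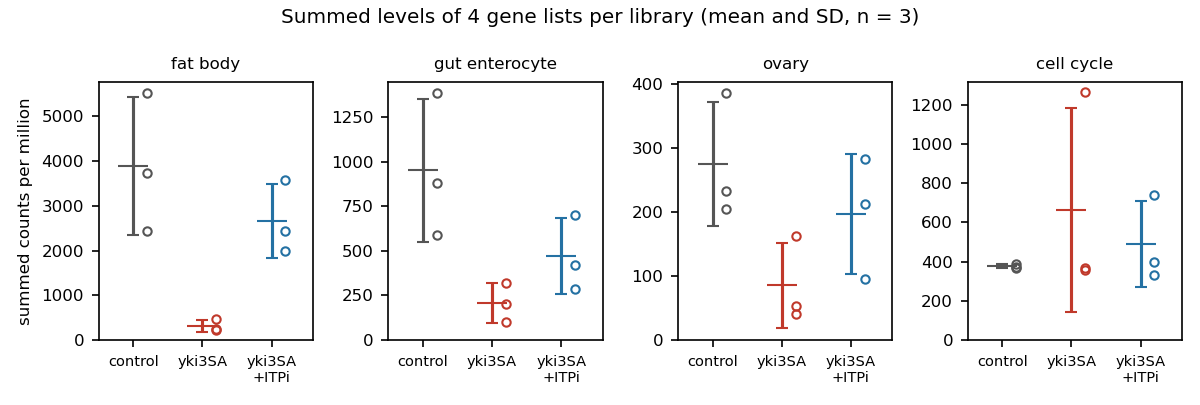
Summed CPM (linear axes from 0) of the fat body, gut enterocyte, ovary and cell cycle lists, with open points for single libraries and mean ± SD of 3 libraries per group. Fat body markers were at 3891 CPM in control, 317 CPM in yki3SA and 2669 CPM in ITP-i, and the cell cycle sum was 1263 CPM in yki3SA library 3 and 742 CPM in ITP-i library 3, against 331 to 400 CPM in the other libraries.

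Among the largest rises were Nazo (FBgn0037562), from 1.02 ± 0.400 to 236 ± 57.4 CPM (log2 7.85, SE 0.31), Srg2 (FBgn0262007), from 6.05 ± 0.812 to 141 CPM (log2 4.54, SE 0.18), and the neprilysin-like gene Nepl9, from 1.26 ± 0.845 to 132 ± 72.2 CPM. The synaptotagmin gene Syt4 rose from 0.820 ± 0.637 to 28.4 ± 1.25 CPM, Erasp from 0.603 ± 0.156 to 21.5 ± 7.43 CPM, CG14302 from 1.20 ± 1.27 to 79.9 ± 9.10 CPM and CG14275 from 0.557 ± 0.381 to 56.2 ± 13.5 CPM. Among the largest falls, the carbonic anhydrase gene CAH5 was at 38.0 ± 16.3 CPM in control and 0.0364 ± 0.0630 CPM in yki3SA, below the level of 3 counts. CG12374 fell from 113 ± 43.7 to 1.20 ± 1.41 CPM. The neuropeptide gene Orcokinin, a marker of enteroendocrine cells, rose from 13.5 ± 2.31 to 94.1 ± 17.4 CPM.

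The count of 3091 fell to 337 with the fat body marker level as a covariate and to 553 with the gut marker level, both chosen after the data were seen. The majority direction depends on the scaling: 53.7% of called genes were higher with TMM, 47.1% with DESeq2 size factors, 45.2% with upper-quartile scaling and 77.9% with total counts, the median log2 fold change of all genes shifting by -0.05, -0.06 and 0.29.

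**Figure D3:**
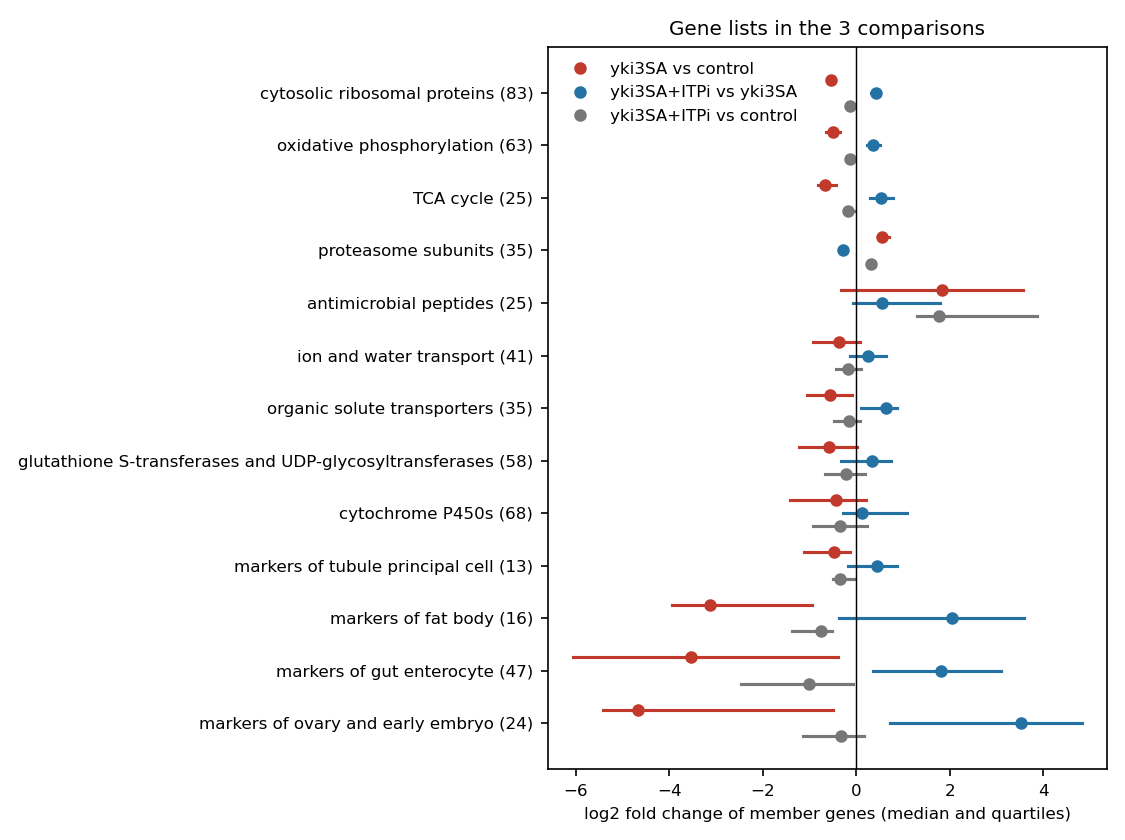
Median (points) and quartiles (lines) of the log2 fold change of the tested members of 13 gene lists, with member numbers in parentheses, in the 3 comparisons. The ribosomal protein median was -0.54 in yki3SA against control, 0.41 in ITP-i against yki3SA and -0.13 in ITP-i against control, while the antimicrobial peptide median was 1.84, 0.55 and 1.76.

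The comparison of ITP-i with yki3SA asks which tubule genes differ when ITP is also knocked down in tumour flies. Of the genes tested, 15 of 25 of the TCA cycle, 28 of 63 for oxidative phosphorylation and 39 of 83 for cytosolic ribosomal proteins rose, and 8 of 35 proteasome genes fell. These list calls were lost with an estimated correlation between genes (adjusted p = 0.59 to 0.76). NKCC fell from 315 ± 48.1 to 44.1 ± 1.44 CPM (log2 -2.84, SE 0.15, adjusted p = 1.4e-05, lower in 3 of 3 libraries, as the naming rule requires). Antimicrobial peptide genes as a list did not pass the test (adjusted p = 0.29). In all, 2126 genes were called, 1089 higher and 1037 lower, and 883 differed at least 2-fold (661 higher, 222 lower). In the same libraries 8 of 16 fat body, 16 of 47 gut and 12 of 24 ovary markers rose.

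Of 25 TCA cycle genes, 15 rose and 0 fell (17 and 0 over the list alone). The members' median was 0.52 (adjusted p = 1.1e-09, or adjusted p = 0.59 with an estimated correlation). mAcon1 rose from 682 ± 32.3 to 1638 ± 105 CPM. Of 63 oxidative phosphorylation genes, 28 rose and 1 fell (39 and 1 over the list alone). The median was 0.36 (adjusted p = 2.7e-08, or adjusted p = 0.76 with an estimated correlation). ATPsynC rose from 1174 ± 133 to 2316 ± 121 CPM. Of 83 cytosolic ribosomal protein genes, 39 rose and 0 fell (65 and 0 over the list alone). Their median was 0.41 (adjusted p = 2.4e-11, or adjusted p = 0.76 with an estimated correlation). RpS2 rose from 915 ± 158 to 1427 ± 47.7 CPM. Of 35 proteasome genes, 8 fell and 0 rose (8 and 0 over the list alone). The list median was -0.29 (adjusted p = 2.3e-04, or adjusted p = 0.76 with an estimated correlation). Rpt6R fell from 16.4 ± 2.26 to 2.89 ± 0.413 CPM and Rpn6 from 185 ± 5.43 to 140 ± 8.40 CPM, the latter a call that ended in most fits without 1 tumour library and with the fat body covariate. With total-count scaling the medians were 0.32 for the TCA cycle, 0.17 for oxidative phosphorylation, 0.22 for ribosomal proteins and -0.49 for the proteasome. The fat body marker sum was 2669 ± 827 CPM in ITP-i against 317 ± 132 CPM in yki3SA.

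Of 35 organic solute transporter genes, 14 rose and 1 fell (14 and 1 over the list alone). The members' median was 0.63 (adjusted p = 6.8e-05, or adjusted p = 0.59 with an estimated correlation). The glucose transporter gene Glut1 rose from 79.1 ± 7.77 to 162 ± 11.5 CPM and the organic anion transporter gene Oatp30B from 238 ± 31.4 to 445 ± 35.2 CPM. Of 58 glutathione S-transferase and UDP-glycosyltransferase genes, 16 rose and 5 fell (17 and 5 over the list alone). The median was 0.34 (adjusted p = 5.9e-04, or adjusted p = 0.59 with an estimated correlation), with a summed level of 4290 ± 152 CPM in yki3SA and 4416 ± 216 CPM in ITP-i. Ugt35C1 rose from 9.20 ± 2.91 to 108 ± 7.62 CPM and Ugt36E1 fell from 56.1 ± 3.30 to 39.4 ± 3.16 CPM. Of 13 principal cell markers, 6 rose and 1 fell (7 and 3 over the list alone). Their median was 0.45 (adjusted p = 0.026, or adjusted p = 0.76 with an estimated correlation). This call ended without yki3SA library 3 (adjusted p = 0.079) and with the fat body or gut marker level as a covariate (adjusted p = 0.19 and 0.066). Uro, the urate oxidase gene of principal cells, rose from 1263 ± 387 to 3300 ± 571 CPM (log2 1.39, SE 0.23, adjusted p = 0.0034), a call that ended with the fat body marker level as a covariate (log2 1.56, adjusted p = 0.056). The ion and water transport list did not pass the test (adjusted p = 0.11) except without yki3SA library 2 (adjusted p = 0.031). Within it Eglp2 and Eglp4 rose from 54.6 ± 13.4 to 225 ± 38.4 CPM and from 80.5 ± 8.46 to 284 ± 64.4 CPM. Total-count scaling gave medians of 0.14 for the transferases and 0.25 for principal cells. The fat body and gut marker sums rose in these same libraries. Of the antimicrobial peptide genes 4 rose and 2 fell (6 and 2 over the list alone), and with the gut marker level as a covariate the list was called higher (adjusted p = 0.05). The bomanin gene BomS3 rose from 7.43 ± 0.753 to 16.5 ± 2.01 CPM, and edin fell from 5.67 ± 2.40 to 0.143 ± 0.145 CPM.

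Of 16 fat body markers, 8 rose and 2 fell (8 and 2 over the list alone). Members had a median of 2.04 (adjusted p = 7.4e-06, or adjusted p = 0.59 with an estimated correlation). Yp2 rose from 53.5 ± 17 to 900 ± 293 CPM, and the larval serum protein gene Lsp1gamma fell from 10.8 ± 13.5 to 0.606 ± 0.118 CPM. Of 47 gut enterocyte markers, 16 rose and 1 fell (19 and 2 over the list alone). For the list the median was 1.82 (adjusted p = 1.5e-07, or adjusted p = 0.64 with an estimated correlation), and their sum was 470 ± 212 CPM in ITP-i. The trypsin gene betaTry rose from 1.37 ± 0.892 to 48.7 ± 29.1 CPM. Of 24 ovary and early embryo markers, 12 rose and 0 fell (16 and 0 over the list alone). The median was 3.53 (adjusted p = 4.6e-07, or adjusted p = 0.59 with an estimated correlation). The vitelline membrane genes Vm26Aa and Vm34Ca rose from 1.01 ± 1.22 to 25.8 ± 15.2 CPM and from 0.643 ± 0.865 to 13.8 ± 7.26 CPM. Of 25 muscle markers, 9 rose and 2 fell (13 and 2 over the list alone). Their median was 0.49 (adjusted p = 0.029, or adjusted p = 0.76 with an estimated correlation). On the scale of total counts the median was 0.30, while the summed level did not rise (2946 ± 161 CPM in yki3SA and 2898 ± 19.5 CPM in ITP-i). That call ended without yki3SA library 2 (adjusted p = 0.069), yki3SA library 3 (adjusted p = 0.13) or ITP-i library 3 (adjusted p = 0.16), with total-count scaling (median 0.30, adjusted p = 0.081), with the replicate block (adjusted p = 0.051) and with the fat body or gut marker level as a covariate (adjusted p = 0.19 and 0.12). Of 16 hemocyte markers, 4 rose and 0 fell (4 and 0 over the list alone). Members had a median of 0.66 (adjusted p = 0.029, or adjusted p = 0.71 with an estimated correlation). On the scale of total counts the median was 0.45, while the summed level did not rise (353 ± 33.4 and 342 ± 27.7 CPM). That call ended without control library 1 or 2 (adjusted p = 0.052 and 0.053), yki3SA library 3 (adjusted p = 0.068) or ITP-i library 1 or 3 (adjusted p = 0.054 and 0.07), with the replicate block (adjusted p = 0.065), with a filter of 5 CPM (adjusted p = 0.42) and with the fat body or gut marker level as a covariate (adjusted p = 0.52 and 0.062).

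mthl8 (FBgn0052475), a methuselah-like receptor gene, had no count in the 6 control and yki3SA libraries and 10.6 ± 1.23 CPM in ITP-i, at least 122-fold higher than the level of 3 counts. Oct-TyrR, a receptor for octopamine and tyramine, rose from 0.295 ± 0.271 to 10.2 ± 1.84 CPM and the sodium channel gene ppk6 from 0.848 ± 0.541 to 16.4 ± 6.56 CPM. CG42704 was at 0.507, 177 and 83.7 CPM in the ITP-i libraries and at 0.197 ± 0.0840 CPM in yki3SA. The alpha-glucosidase gene tobi rose from 2.10 ± 0.471 to 37.8 ± 10.6 CPM and the carotenoid uptake gene ninaD from 3.33 ± 0.527 to 57.1 ± 11.4 CPM. Among the falls, CG31091 (FBgn0051091) dropped from 62.8 ± 5.80 to 0.187 ± 0.128 CPM (log2 -8.35, SE 0.63), the multicopper oxidase gene Mco3 (FBgn0039387) from 69.5 ± 13.2 to 0.385 ± 0.132 CPM (log2 -7.48, SE 0.43), Sodq from 58.9 ± 11.0 to 0.741 ± 0.178 CPM and CG31089 from 24.4 ± 2.93 to 0.565 ± 0.133 CPM. The antisense RNA asRNA:CR43259 fell from 19.0 ± 4.23 to 2.03 ± 0.702 CPM, a value that depends on a strand setting that is not stated. These 5 genes follow one another in the reference annotation when untested genes are skipped. Culd fell from 197 ± 32.1 to 26.4 ± 6.95 CPM, and lncRNA:roX1, a noncoding RNA of dosage compensation, from 41.0 ± 4.40 to 4.49 ± 0.912 CPM.

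Of the 3091 genes called in yki3SA against control, 1385 (44.8%) moved back in ITP-i, 664 that had risen and then fell and 721 that had fallen and then rose, and 59 moved further (47 upward, 12 downward). If the calls of the comparisons were independent, 320 genes would move back and 321 further, but both comparisons share the yki3SA libraries, which alone makes their fold changes negatively correlated. Across genes the correlation of the fold changes was -0.53. In simulated counts with no difference between groups its mean was -0.50, and in those in which ITP-i equals yki3SA it was -0.22 to -0.15. The correlation thus exceeds the simulations with a yki3SA effect but not those without any, and by itself does not settle a reversal. The covariance was -0.67, against means of -0.12 in the simulations with no difference and -0.11 in those in which ITP-i equals yki3SA. Genes that moved back numbered at most 2 in the simulations with no difference. At most 2 genes were called in either comparison there, so that count was fixed in advance. Among the 8 genes with the smallest p, CG7968 went from 215 ± 24.8 to 14.3 ± 2.54 and 206 ± 6.17 CPM in control, yki3SA and ITP-i, and the biotinidase gene Btnd from 168 ± 42.0 to 10.9 ± 2.50 and 138 ± 22 CPM. smp-30 went from 664 ± 59.9 to 72.2 ± 9.55 and 459 ± 54.5 CPM, the sarcoplasmic calcium-binding protein gene Scp2 from 1010 ± 238 to 77.5 ± 13.5 and 540 ± 39.2 CPM, and CG9512 from 3643 ± 959 to 48.1 ± 10.7 and 653 ± 24.8 CPM. CG7402 went from 47.7 ± 7.41 to 4.12 ± 0.152 and 33.3 ± 7.35 CPM, CG14722 from 25.9 ± 1.01 to 105 ± 14.9 and 32.1 ± 1.10 CPM, and NKCC is the eighth.

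Without yki3SA library 2, ITP-i library 1 or ITP-i library 2, the count of 2126 was 1371, 1028 or 1308 and that of genes moved back was 902, 693 or 876, and with the fat body or gut marker level as a covariate (chosen after the data were seen) they were 349 or 1187 and 173 or 343. With total-count scaling 28.2% of called genes were higher instead of 51.2%, and with upper-quartile scaling 63.1%, the median of all genes shifting by -0.20 and 0.06.

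The comparison of ITP-i with control asks what remains different in tubules of tumour flies with the knockdown. Of 25 antimicrobial peptide genes 13 were higher than control, and of 68 cytochrome P450 genes 15 were lower and 4 higher. Both list calls were lost with an estimated correlation between genes (adjusted p = 0.1 and 0.45). AttD was at 81.5 ± 23.0 CPM against 0.396 ± 0.145 CPM (log2 7.67, SE 0.31, adjusted p = 1.6e-06), and Srg2 at 688 ± 105 CPM against 6.05 ± 0.812 CPM (log2 6.83, SE 0.19, adjusted p = 1.2e-07). In all, 1077 genes were called, 653 higher and 424 lower, and 659 differed at least 2-fold (461 higher, 198 lower). Of these calls, 63.3% were also called the same way in yki3SA against control (406 higher and 276 lower in both). Both comparisons share the control libraries. Their fold changes correlated at 0.60 across genes, against a mean of 0.50 in simulated counts with no difference between groups. At most 1 gene was called the same way in both there. That count is no benchmark, since at most 2 genes and 1 gene were called in the comparisons at all.

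Of 25 antimicrobial peptide genes, 13 rose and 0 fell (17 and 2 over the list alone). For the list the median was 1.76 (adjusted p = 1.0e-20, or adjusted p = 0.1 with an estimated correlation). DptA was at 175 ± 16.0 CPM, DptB at 52.9 ± 8.35 CPM and Dro at 23.4 ± 4.99 CPM, against 2.88, 2.79 and 0.226 CPM in control. Of 33 IMD and Toll components, 6 rose and 1 fell (6 and 1 over the list alone). The median was 0.13 (adjusted p = 0.017, or adjusted p = 0.26 with an estimated correlation). PGRP-SB1 rose from 3.91 ± 1 to 106 ± 51.2 CPM. Of 68 cytochrome P450 genes, 15 fell and 4 rose (25 and 7 over the list alone). Their median was -0.35 (adjusted p = 9.2e-04, or adjusted p = 0.45 with an estimated correlation), and Cyp6g1 was at 447 ± 68.7 CPM. Of 58 glutathione S-transferase and UDP-glycosyltransferase genes, 11 fell and 2 rose (13 and 4 over the list alone). Members had a median of -0.23 (adjusted p = 0.015, or adjusted p = 0.45 with an estimated correlation). This call ended with the gut marker level as a covariate (adjusted p = 0.1). Of 35 proteasome genes 2 rose and 0 fell (0 and 0 over the list alone). For the list the median was 0.32 (adjusted p = 8.2e-04, or adjusted p = 0.84 with an estimated correlation). Of 47 gut enterocyte markers 9 fell and 2 rose (12 and 4 over the list alone). The median was -1.01 (adjusted p = 0.0044, or adjusted p = 0.84 with an estimated correlation). This call ended with their own level as a covariate (adjusted p = 0.39). Total-count scaling gave medians of 0.22 for the IMD and Toll list and -0.13 for the transferases.

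For cytosolic ribosomal proteins, 0 of 83 genes were called by edgeR (2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom), while the list was called lower with a median of -0.13 (adjusted p = 0.014). Oxidative phosphorylation genes had a median of -0.14 with 1 of 63 fallen (adjusted p = 0.015), ion and water transport genes -0.19 with 4 of 41 fallen and 3 risen (adjusted p = 0.039), lipid metabolism genes -0.26 with 9 of 41 fallen and 3 risen (adjusted p = 0.035) and fat body markers -0.75 with 3 of 16 fallen (adjusted p = 0.03). Over the list alone these counts were 0 for oxidative phosphorylation, 9 fallen and 3 risen for ion and water transport, 12 fallen and 4 risen for lipid metabolism and 3 fallen for fat body. Principal cell markers (median -0.36, 2 of 13 fallen and 1 risen, or 6 and 1 over the list alone) and muscle markers (median 0.30, 1 of 25 risen, or 1 over the list alone) were called at adjusted p = 0.05. With an estimated correlation each of these 7 lists had adjusted p = 0.84. The summed levels of the ribosomal protein, oxidative phosphorylation, principal cell and fat body lists differed from control by less than the SD between control libraries. Those of the other 3 lists differed by more. In control and ITP-i, ion and water transport was at 23232 ± 1339 and 19298 ± 639 CPM and lipid metabolism at 6003 ± 127 and 5517 ± 103 CPM. Muscle markers were at 2247 ± 42.4 and 2898 ± 19.5 CPM.

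Total-count scaling ended the calls of the ribosomal protein (median -0.04, adjusted p = 0.054), oxidative phosphorylation (median -0.05, 0.054), ion and water transport (median -0.08, 0.054), lipid (median -0.17, 0.056), principal cell (0.065) and muscle (0.054) lists in ITP-i against control. The replicate block ended those of the lipid (0.056), principal cell (0.06) and muscle (0.058) lists, and a filter of 5 CPM those of the lipid (0.058), principal cell (0.076), muscle (0.058) and fat body (0.058) lists. The 13 list calls became 9 with the fat body marker level and 5 with the gut marker level as a covariate, and 7 without both tumour libraries numbered 3. Without ITP-i library 3, the oxidative phosphorylation (adjusted p = 0.085), ion and water transport (0.1), lipid (0.18), fat body (0.1), principal cell (0.21) and muscle (0.22) lists lost the call. Without control library 1, ion and water transport (0.12), oxidative phosphorylation (0.068) and principal cells (0.16) lost it. The fat body call also ended without control library 3 (0.12) or ITP-i library 2 (0.074). The ion and water transport call ended without yki3SA library 1 or 2 (0.054 and 0.057). The principal cell call ended without any 1 yki3SA library (0.059, 0.062 and 0.07), and the muscle call without any 1 library other than ITP-i library 2 (0.053 to 0.22). Of 24 ovary markers 0 were called by edgeR, at an unadjusted p under 0.05, by DESeq2 or by limma-voom, and of 16 hemocyte markers edgeR called 0 (7 at an unadjusted p under 0.05, 5 by DESeq2, 2 by limma-voom).

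By the naming rule the largest rises were mthl8, Nepl9 (694 ± 198 against 1.26 ± 0.845 CPM), AttD and Srg2, and the largest falls were CG31091 (0.187 ± 0.128 against 124 ± 66.5 CPM), Mco3 (0.385 ± 0.132 against 114 ± 46.5 CPM), LysC (0.201 ± 0.180 against 28.1 ± 17.7 CPM) and Sodq (0.741 ± 0.178 against 77.7 ± 28.0 CPM). Nepl9 and Srg2 also rose in ITP-i against yki3SA (log2 2.40 and 2.29, adjusted p = 0.0067 and 3.8e-05). Without control library 1 or 3 or ITP-i library 1 or 2, the count of 1077 was 717, 714, 642 or 683. With the fat body or gut marker level as a covariate (chosen after the data were seen) it was 640 or 429, and with total-count scaling 71.9% of called genes were higher instead of 60.6%.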

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

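Total-count scaling and the fits without 1 library were planned, while the other tests in this part (covariates, simulations, control side and neighbours), and the thresholds for reading each of them, were chosen only after the results were seen. Earlier thresholds, on the size of the median and its range without 1 library, had counted the fat body and gut covariate values of the first pattern and the fat body values of the second against those tissues. The thresholds used here also ask that the median exceeds its spread across genes and that most members are called, for genes that moved back in both comparisons. In ITP-i against yki3SA alone, the gut covariate value of the rises had counted against gut. The tests of the first pattern had been run on its called genes alone, where total-count scaling counted against the choice of scaling, and they now cover all tested members.

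In 22 genes, yki3SA and ITP-i differed from control in opposite directions, and the difference between yki3SA and ITP-i itself passed the test in each. CG6912, named here after its values were seen, was at 1.03 ± 0.429, 0.191 ± 0.0723 and 6.22 ± 0.603 CPM in control, yki3SA and ITP-i (log2 5.02 for ITP-i against yki3SA, adjusted p = 1.1e-04). tobi (log2 4.18, adjusted p = 3.3e-05) and ninaD (log2 4.10, adjusted p = 1.4e-05) also fell in yki3SA and were above control in ITP-i. The call of tobi against control (log2 1.01) ended without control library 1 or 3 or ITP-i library 1 or 3 (log2 1.0, 0.87, 1.02 and 0.79) and with the fat body (log2 0.89, adjusted p = 0.1) or gut marker level (log2 1.12, adjusted p = 0.093) as a covariate.

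The first pattern is the fall of the 171 oxidative phosphorylation, TCA cycle and ribosomal protein genes tested in yki3SA (median log2 -0.55, SD 0.43 across genes, 142 called lower), in libraries where fat body and gut markers also fell, Yp2, an abundant one, from 1305 to 53.5 CPM. With total counts only, the median was -0.27 (SD 0.43, between -0.34 and -0.22 without 1 library) and 76 of the 171 genes were called lower. By the thresholds used here these values leave the choice of scaling open. Summed CPM of total counts still fell from control to yki3SA, for the TCA cycle from 13715 ± 388 to 9313 ± 249. For oxidative phosphorylation the sums were 23302 ± 769 and 18131 ± 1142, and for ribosomal proteins 99593 ± 4190 and 82810 ± 8103. For these sums, this argues against TMM scaling as the sole source of the fall. RNA of fat body in the control libraries stays open: with the fat body marker level as a covariate the median was -0.44 (SD 0.43, between -0.59 and -0.41), but the median SE went from 0.13 to 0.26 and 3 calls were left, and with the gut marker level, for RNA of gut enterocytes, it was -0.47 (SD 0.40) with a median SE of 0.22 and 4 calls left, mainly because either covariate follows the groups and takes precision. At the preset correlation the oxidative phosphorylation, TCA cycle and ribosomal protein lists were still called lower with the fat body covariate (median -0.50, -0.60 and -0.42, adjusted p = 6.2e-08, 1.4e-07 and 3.6e-07) and with the gut covariate (median -0.43, -0.51 and -0.48, adjusted p = 2.0e-07, 2.4e-06 and 5.9e-10), but with an estimated correlation (0.69, 0.49 and 0.87) they were not called even without a covariate (adjusted p = 0.41, 0.3 and 0.42), so these calls exclude neither tissue. Each covariate removed its own markers only in part (fat body median -3.14 to -1.35 and gut median -3.54 to -1.67), so adhering tissue lost from tumour flies may contribute as well as an effect of the tumour on tubule cells (all 16 fat body genes and 47 of 52 gut genes are detected in these libraries, and 0 and 1 of them are on another list).

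The second pattern is the 1385 genes whose change in yki3SA moved back in ITP-i, for which the design does not separate a weaker tumour, dilution of Gal4 over more UAS transgenes and an action of ITP on the tubules. At most 1 gene moved back in simulations in which ITP-i equals yki3SA. At most 1 gene was called in ITP-i against yki3SA in them, so that count was fixed in advance and cannot weigh shared libraries. The covariance of the fold changes was -0.13 to -0.09 in them, against -0.67 observed. The observed covariance exceeds in size what the spread between libraries of a group gives for independent genes. Shared libraries are not excluded as the whole cause of the opposite fold changes across genes. Genes of a list were correlated here, and the labels leave open whether libraries of a group are splits of a single pool. Part or all of the excess may come from shared libraries, since 3 libraries per group cannot be split into parts of at least 2. Among the 1293 genes that changed at least 2-fold in yki3SA, 85.6% had an ITP-i mean on the control side of the yki3SA mean. In the simulations in which ITP-i equals yki3SA it was 57.92% to 61.56%. These simulations hold no batch and draw genes independently, while a batch can move many genes together. They thus cannot weigh a library batch, which stays open whether or not it runs along the tumour direction. RNA of fat body in the control and ITP-i libraries stays open as well: with its marker level as a covariate the 664 rises had a median of -0.62 (SD 0.67, before -0.65) and the 721 falls 1.0 (SD 1.43, before 1.10), but the median SE went from 0.14 to 0.22 and from 0.19 to 0.29, and 79 and 178 calls were left. RNA of gut enterocytes stays open too: with its marker level as a covariate the medians were -0.63 (SD 0.61) and 1.07 (SD 1.30) with 349 of 664 and 463 of 721 calls left, but in yki3SA against control, which moving back also needs, 124 and 247 were left and the median SE went from 0.14 to 0.25 and from 0.19 to 0.31.

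The third pattern is the 44 genes at least 8-fold apart in ITP-i from both other groups (16 lower, 28 higher). With untested genes skipped, they formed 5 adjacent pairs in the reference gene order, 4 of them from Sodq, Mco3, CG31091, CG31089 and asRNA:CR43259. In 10000 random gene sets the mean was 0.19 and the highest 4 (permutation p = 1e-04, the smallest these sets can give). A sequence difference of the ITP-i flies at a few loci may give such clusters. The 100 genes equally far apart in yki3SA formed 16 adjacent pairs (mean of random sets 1.0). These include neighbours of the same family, such as the chorion genes Cp7Fa, Cp7Fb, Cp7Fc, Cp36 and Cp38. They are therefore no control for a difference at a locus, and the comparison cannot decide. A library batch of the ITP-i libraries cannot be told apart from genotype, since 0 ITP-i libraries share a stated batch with another group. Genetic background, RNAi and batch all remain open.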

How the results depend on the processing

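Fits with a covariate, without the marker genes and without both tumour libraries numbered 3 were chosen after seeing the data. Counts for yki3SA against control, ITP-i against yki3SA, ITP-i against control and genes moved back stayed within 1.5 times the reported 3091, 2126, 1077 and 1385 with DESeq2, limma-voom, DESeq2 size factors, upper-quartile scaling, no filter, at least 5 CPM in 3 libraries, robust = TRUE, 2-group fits, the replicate block and without the marker genes (3012, 2062, 1074 and 1331). A fold of at least 2 gave 1293, 883, 659 and 473, as a stricter criterion must. Without 1 library in turn they ran from 2177 to 3150, from 1028 to 2047, from 642 to 1095 and from 693 to 1238, with 1 library fewer each time; yki3SA library 2 (1371 and 902), ITP-i library 1 (1028, 642 and 693), ITP-i library 2 (1308, 683 and 876) and control libraries 1 and 3 (717 and 714) moved a count by over 1.5 times. Without both tumour libraries numbered 3 they were 2577, 1362, 975 and 897. The fat body covariate gave 337, 349, 640 and 173 and the gut covariate 553, 1187, 429 and 343. Total-count scaling gave 2361 genes moved back. It shifted the median of all genes by 0.29 in yki3SA against control and by -0.20 in ITP-i against yki3SA. These opposite shifts favour calls of a rise followed by a fall, and their share in the larger count was not tested.

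List calls (17, 12 and 13 of 30) became 0, 0 and 0 with an estimated correlation, where 3, 1 and 2 lists had an unadjusted p under 0.05. For ITP-i against control they became 4 with fry, which does not compare a list with other genes, 7 with total-count scaling, 7 without both tumour libraries numbered 3 and 5 with the gut covariate. Without 1 library they ran from 16 to 19, from 10 to 12 and from 7 to 15, with 7 without ITP-i library 3. The cause was not tested. Other splits of the libraries, which mix the groups, called up to 20, 13 and 16 lists at the preset correlation. The number of list calls therefore does not set the real groups apart. The cell cycle list turned direction in yki3SA against control without yki3SA library 3 (adjusted p = 0.046, range without 1 library 0.043 to 0.46 and over all alternatives 0.0075 to 0.97) and without both tumour libraries numbered 3 (0.0075), and in ITP-i against yki3SA likewise (7.6e-05, range without 1 library 7.6e-05 to 0.93, and 0.0033). asRNA:CR43259 in yki3SA against control went to a log2 of 0.08 with the fat body covariate, and the cause was not tested. Of 90 list results 39 kept direction and call under each alternative, and of 442 named gene results 161 did.

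With a block for the replicate number, which the labels do not call a batch, the counts were 3189, 2287, 1137 and 1491 genes and 15, 10 and 10 lists. Libraries of the same number correlated across genes, within groups, between -0.08 and 0.17, with 3 of 9 pairs above 0.1. In 11 of 18 comparisons of a library with another group, the best match among its 3 libraries had the same number. If the number had no meaning, each of the 3 would be equally likely to match best. The comparisons reuse the same libraries and are not independent, so a batch shared by libraries of the same number stays open. In simulated counts in which 9776 of 10031 genes were unchanged, a 1.5-fold change was mostly missed (7.7% recovered). Adjustment is less strict where many genes differ. In yki3SA against control, 75 of 83 ribosomal protein genes, with a median log2 of -0.54, were called lower.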

Other observations

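The pathway tests, the clock genes named here and the reading of the splits of libraries were chosen only after the results were seen.

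Among the 264 pathways of the deposited annotation column, 68 were called by camera in yki3SA against control, 54 in ITP-i against yki3SA and 24 in ITP-i against control. Degradation of the branched amino acids valine, leucine and isoleucine fell in yki3SA (24 of 31 genes fallen, 0 risen, median log2 -1.04, adjusted p = 1.5e-13, or adjusted p = 0.63 with an estimated correlation). It rose in ITP-i against yki3SA (20 risen, 0 fallen, median 0.85, adjusted p = 2.7e-12, or adjusted p = 0.77 with an estimated correlation). Genes of ribosome biogenesis rose in yki3SA (41 of 65 risen, 3 fallen, median 0.55, or 0.84 with total-count scaling, adjusted p = 1.5e-06, or adjusted p = 0.64 with an estimated correlation), where ribosomal protein genes fell. They fell in ITP-i against yki3SA (27 fallen, 1 risen, median -0.43, adjusted p = 1.6e-06, or adjusted p = 0.89 with an estimated correlation). SNARE genes of vesicle fusion rose in yki3SA (12 of 20 risen, 0 fallen, adjusted p = 1.7e-04, or adjusted p = 0.63 with an estimated correlation) and fell in ITP-i against yki3SA (12 fallen, 0 risen, adjusted p = 1.2e-04, or adjusted p = 0.77 with an estimated correlation). Genes that regulate the actin cytoskeleton were higher than control in yki3SA (26 of 66 risen, 2 fallen, adjusted p = 0.0011, or adjusted p = 0.64 with an estimated correlation) and in ITP-i (9 risen, 0 fallen, adjusted p = 0.0063, or adjusted p = 0.98 with an estimated correlation). Fat body and gut markers moved in the same libraries.

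Transcripts encoded by the mitochondrial genome took 6.4%, 6.7% and 8.0% of the counts in control, 5.3%, 4.4% and 4.7% in yki3SA and 7.2%, 6.1% and 7.0% in ITP-i. The clock gene tim was at 465, 609 and 721 CPM in control, 387, 387 and 330 CPM in yki3SA and 73.5, 88.1 and 50.1 CPM in ITP-i (log2 -2.38 for ITP-i against yki3SA, SE 0.23, adjusted p = 1.9e-04). In ITP-i against control, the clock genes vri (168 ± 46.3 and 91.1 ± 17 CPM, adjusted p = 0.022) and Pdp1 (325 ± 67.6 and 199 ± 26.6 CPM, adjusted p = 0.03) were lower, while per (adjusted p = 0.11), Clk (adjusted p = 0.9) and cry (adjusted p = 0.85) did not pass the test, and the hour of dissection is not stated. The circadian rhythm pathway was not called in any comparison (adjusted p = 0.74, 0.58 and 0.88). The cytokine gene upd3 rose in yki3SA from 0.892 ± 0.645 to 8.82 ± 5.73 CPM, and upd2 was at 5.92 ± 1.76, 1.30 ± 0.350 and 0.467 ± 0.139 CPM in control, yki3SA and ITP-i. The adenosine deaminase gene Adgf-A was at 9.82 ± 0.883, 74.4 ± 9.65 and 35.0 ± 3.31 CPM.

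The lists not called in yki3SA against control were V-ATPase subunits (4 of 25 rose, 3 fell, adjusted p = 0.68), hormone receptors and cyclic nucleotide signalling (4 of 35 rose, 5 fell, adjusted p = 0.59), JAK-STAT and JNK (6 of 31 rose, 5 fell, adjusted p = 1), purine metabolism (7 of 25 rose, 6 fell, adjusted p = 0.66), oxidative stress and heat shock (4 of 34 rose, 5 fell, adjusted p = 0.88) and insulin and FOXO (6 of 30 rose, 6 fell, adjusted p = 0.87). Others were cell cycle and DNA replication (3 of 35 rose, 0 fell, adjusted p = 0.48), Yorkie targets and progenitor genes (8 of 24 rose, 0 fell, adjusted p = 0.085), septate and adherens junctions (8 of 28 rose, 1 fell, adjusted p = 0.11, or adjusted p = 0.05 without yki3SA library 1), and markers of stellate cells (2 of 9 rose, 2 fell, adjusted p = 0.98), enteroendocrine cells (2 of 12 rose, 1 fell, adjusted p = 0.78), muscle (3 of 25 rose, 1 fell, adjusted p = 0.81) and neurons (1 of 13 rose, 0 fell, adjusted p = 0.88). For V-ATPase, JAK-STAT and JNK, insulin and FOXO, stellate, enteroendocrine and muscle genes the median (-0.17, -0.06, 0.11, -0.31, -0.81 and -0.22) differs in sign from the mean (0.11, -0.03, -0.08, 0.30, -0.08 and 0.04) or from the direction of the test (lower, higher, higher, higher, higher and lower). Oxidative stress genes had a median of 0.00 and a mean of 0.09, with the test pointing lower. With total-count scaling the medians turned to 0.11 for V-ATPase, 0.22 for hormone receptors, 0.20 for JAK-STAT and JNK, 0.07 for muscle and 0.08 for neurons, and the stellate median was -0.02. Of the male reproductive tract list 1 gene was tested, Est-6, at 15.7 ± 10, 2.46 ± 0.801 and 14.1 ± 4.74 CPM in control, yki3SA and ITP-i. In ITP-i against control, the V-ATPase list (median -0.30, adjusted p = 0.052) and the glycolysis list (median -0.11, or -0.01 with total-count scaling, adjusted p = 0.052) were just above the threshold. The V-ATPase list was called lower with a filter of 5 CPM (adjusted p = 0.015) and without control library 2, control library 3 or ITP-i library 1 (0.03, 0.03 and 0.049), the glycolysis list without control library 2, control library 3 or ITP-i library 2 (0.025, 0.006 and 0.033) or with the fat body covariate (0.039), and the TCA cycle list without control library 2 or 3 (0.045 and 0.043).

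With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real splits called 3091, 2126 and 1077 genes, more than the 9 other splits in each comparison, of which the highest called 0 (at an unadjusted p under 0.05 the real splits gave 4244, 3717 and 2472 and the highest others 543, 807 and 1003), and 1 of the 10 splits, the real one, was as large. For list calls 3, 3 and 2 of the 10 splits called as many as the real 17, 12 and 13, and the highest others called 20, 13 and 16. The number of list calls at the preset correlation thus does not set the real groups apart from mixed ones. For genes moved back, 1 of the 100 splits drawn, the real one, gave 1385, and the highest other gave 706. Such splits ask only whether the groups differ at all, so they do not bear on a reversal.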
